A study of Arabidopsis with 6 samples.

How the data were processed

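RNA was measured in 6 libraries of Arabidopsis seedlings, 1 for each of 6 groups: WT and the PCD8 RNAi-21 line, each grown in the dark for 4 days and sampled at 0, 0.5 or 2 h of light. Per the labels' protocols, total RNA was extracted with TRIzol and libraries followed standard Illumina protocols. The tissue is given as leaf. HISAT and Bowtie2 are named, without version, in the submitters' processing notes. The quantification tool, genome build and annotation are not given in the sources used here. The deposited values were read as FPKM, a value scaled for transcript length and library size, which the authors computed before deposit. No header or label names the unit. It was inferred from non-integer values whose sums differ between libraries and from locus names of the kind Cufflinks writes, and a table of TPM that holds only part of the genes is not excluded. No counts were used, so the depth is unknown and no counting interval is given. Low values showed no whole-read steps from which depth could be taken.

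Each library listed 19763 genes, of which 19532 matched a locus of the RefSeq TAIR10.1 table by identifier. That table was used only for names and gene types. A symbol was found for 8494 listed genes, and 139 identifiers were unnamed loci of the quantification. Of the 27550 protein-coding loci in the table, 8578 were not listed, so the deposited set is a part of the genome. Exact zeros occurred in 280 genes in at least 1 library and can be failed estimates, so a gene at 0 is only called listed at 0.

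Values were transformed as log2(FPKM + 1), and genes with an FPKM of at least 1 in at least 1 library were kept, 18441 in all. Comparisons of 1 library with 1 library have no test. They are reported as counts of genes that differ by at least 1 on this scale, called 2-fold here. These comparisons were RNAi-21 against WT at each of the 3 times, each light time against 0 h in each genotype, and the difference of the light responses. The genotype effect over the 3 times and the light effects over both genotypes came from 1 limma fit with light time and genotype as additive terms and a variance trend, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit has 2 residual degrees of freedom, and a prior of 4.93 degrees of freedom was borrowed across genes. Its error is the departure from an equal genotype difference at every time, so its p-values measure that spread and not the spread between plants. In 5 simulations of this genotype comparison on 18441 genes with 200 changed genes, 99.8% of those changed by 1 and 100% of those changed by 2 on the log2 scale were recovered, with 20.2 false calls on average. That is a larger share of the calls than the threshold of 0.05 allows. The noise was independent and normal with the error of the fit, without a genotype difference that varies with light. Only genes with a mean above 2 were changed, so the recovery does not carry over to the real libraries.

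Before the data were examined, 21 gene lists with 389 members were fixed, of which 353 members are listed. They cover tetrapyrrole synthesis, light harvesting, photosystems, carbon fixation, light signalling, photoreceptors and PIFs, early stress, antioxidants, heat shock, salicylate, jasmonate, ethylene, auxin, flavonoids, carotenoids, plastid transcription, cell cycle, seed, root, xylem and stomata. Each list's median difference was placed among 10000 random lists of the same size matched in 20 bins of mean expression. The percentile describes these libraries and is not a test. Of 40 random lists with no effect, 2 fell outside the 2.5 to 97.5 percentiles, and all 40 lists shifted by 0.5 lay above them. These were lists of random genes, so they do not show how often lists of genes that move together lie outside by chance. Medians for organelle-encoded and small nuclear and nucleolar RNA genes were added after seeing the data.

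The genes named were set by a rule: in each comparison of RNAi-21 with WT and each WT light comparison, the 5 highest and 5 lowest differences among genes with a symbol and an FPKM of at least 5 in either library. For the genotype test, up to 10 genes each way with a symbol, past the threshold and with the same sign at all 3 times were named, and where fewer than 5 passed, those with the smallest p were added as not passing. For each list described, up to 4 members with the largest differences were named. Genes named outside the rule are said to be. Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter of 5, median-ratio scaling, organelle genes left out with totals equalised, a 4-fold threshold, no variance trend, no light time term, and leaving out each time. Analyses used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.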

Results

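Transcript levels were measured by RNA sequencing in Arabidopsis seedlings of the wild type (WT) and of a line labelled PCD8 RNAi-21, in which RNA interference is directed at PCD8. Seedlings were grown in the dark for 4 days and were sampled at that point (0 h) or after 0.5 h or 2 h of light. Each of the 6 groups held 1 library, so no value below has a replicate error. The values were read as FPKM, and 19763 genes were listed per library. The FPKM summed to between 757504 and 891009 per library, and the read depth behind them is unknown. Of the listed genes, 18441 reached an FPKM of 1 in at least 1 library and entered the comparisons. Differences are given on the log2(FPKM + 1) scale, which understates the change of weakly expressed genes.

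The level of the targeted gene is not analysed here, because no locus in the gene name table carried the name PCD8 as a symbol or synonym. The labels of the RNAi-21 libraries therefore have no check from the target transcript.

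The first question was which genes differed between RNAi-21 and WT across the 3 light conditions. HEI10 (AT1G53490), a RING finger protein of meiotic crossover formation, rose most among the named genes, from an FPKM of 2.07 in dark-grown WT to 28.9 in dark-grown RNAi-21. Its genotype effect was 3.34 ± 0.10 (SE) with an adjusted p of 8.2e-05 in limma, and it was higher by 3.24 to 3.49 at the 3 times. A sequence or background difference between the lines was not examined, at this locus or at any other. XTH7 (AT4G37800), a cell wall xyloglucan endotransglucosylase, rose by 1.28 ± 0.10 (adjusted p = 0.008, limma). VSP2 (AT5G24770), a jasmonate-responsive storage protein, rose by 1.16 ± 0.14 (adjusted p = 0.04, limma), at FPKM between 1.23 and 7.76. The retroelement transcript SADHU3-2 (AT3G42658) and the defence-priming gene AZI1 (AT4G12470) rose by 1.03 and 0.83, with AZI1 at 123 to 217 in WT and 221 to 350 in RNAi-21. In the other direction, the floral repressor SVP (AT2G22540) had a genotype effect of -1.19 ± 0.11 (adjusted p = 0.021, limma) and an FPKM of 19.4 in WT against 6.88 in RNAi-21 in the dark. HGO (AT5G54080), an enzyme of tyrosine breakdown, had an effect of -0.81 ± 0.09, and the small nuclear RNA gene U4.2 (AT3G06900) one of -1.12 ± 0.14. The tonoplast aquaporin BETA-TIP at -0.69 and the nicotianamine synthase NAS2 at -0.76 did not pass the test, both with an adjusted p of 0.071 in limma.

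In total 18 genes rose and 13 fell in RNAi-21 in the additive limma fit, and all 31 had the same sign at all 3 times. Of these, 8 have a symbol and 4 are encoded by the plastid or mitochondrial genome. Among the gene lists fixed before the data were examined, VSP2 in the jasmonate list was the only member that passed over all genes tested. Adjusted over the list alone, VSP2 again passed, and 1 member fell in each of the light signalling, heat shock, ethylene, seed and xylem lists. No member of the tetrapyrrole, light-harvesting, photosystem, carbon fixation, early stress or auxin lists passed either way, and 2294 genes had an unadjusted p under 0.05. The fit has 2 residual degrees of freedom, and its error is how far the genotype difference varied between the 3 times. The count depends on which times enter, with 176 calls without the 0 h libraries, 155 without the 0.5 h libraries and 6 without the 2 h libraries. Each of these fits has 1 residual degree of freedom, so its error is poorly known and the counts do not show which light times matter. Of the 31 genes, 15 passed without a variance trend, when VSP2, SADHU3-2, AZI1, U4.2 and HGO were lost. Without a light time term 7 passed, and without the 2 h libraries 5, and in both cases HEI10 was the only gene with a symbol that kept its call.

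**Figure D1:**
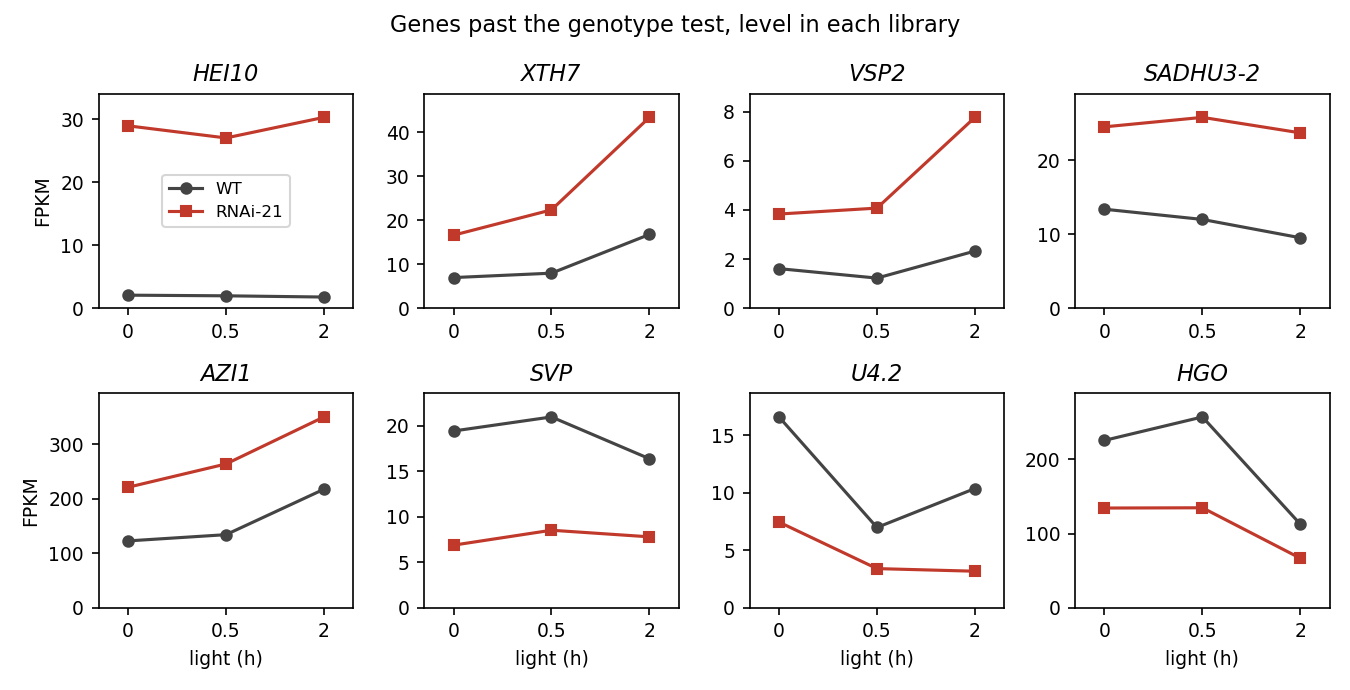
FPKM of the 8 named genes that passed the genotype test, plotted against hours of light, with 1 library per point, WT in grey circles and RNAi-21 in red squares. HEI10 stays between 1.78 and 2.07 in WT and between 27.0 and 30.3 in RNAi-21, and SVP, U4.2 and HGO are lower in RNAi-21 at each time.

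The next question was how the genotypes differed in each light condition, which rests on size alone because each side is 1 library. In the dark, 31 genes were at least 2-fold higher and 73 at least 2-fold lower in RNAi-21. HEI10 was higher by 3.28, XTH7 by 1.14, the small nuclear RNA gene U2.5 by 0.94, AZI1 by 0.84 and SADHU3-2 by 0.83. The small nuclear RNA genes U1.5 (AT1G08115) and U2.7 (AT5G61455) were lower, with differences of -3.00 and -1.45. SVP differed by -1.37, and PTAC15 (AT5G54180), a protein of the plastid transcription complex, by -1.19 with an FPKM of 79.8 in WT and 34.3 in RNAi-21. The egg cell regulator RKD1 (AT1G18790) was listed at 17.41 in dark-grown WT and at 0 in the other 5 libraries. With a pseudocount of 0.1 these counts became 131 higher and 231 lower, and with a filter of 5 they became 20 and 42. With organelle-encoded genes left out and library totals then equalised, a setting called totals equalised below, they were 37 and 50, which moves the share of higher calls from 29.8% to 42.5%.

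In the dark the median of the photosystem list lay below nearly all random lists, and those of the other photosynthesis lists did not. Nuclear-encoded photosystem and electron transport genes had a median difference of -0.19 over 26 members, at percentile 1.31 of 10000 random lists matched on expression, with 21 members below 0. The Rieske protein gene PETC differed by -0.61 and the oxygen-evolving complex gene PSBO1 by -0.51. Light-harvesting genes had a median of -0.15 (percentile 6.50, 20 members), with LHCB1.5 at -0.79 and LHCA5 at -0.69, and carbon fixation genes one of -0.13 (percentile 16.47, 13 members). The tetrapyrrole list, the pathway of chlorophyll and haem, had a median of -0.02 over 29 members in the dark, which turns to 0.04 with totals equalised. In it, the protochlorophyllide reductase genes PORA and PORB were higher by 0.54 and 0.28. Heat shock genes had a median of -0.22 (percentile 0.12, 16 members), with HSP17.6A at -1.05, the only member at least 2-fold lower. Salicylate and defence genes had a median of 0.19 (percentile 98.28, 13 members), with NIMIN1 at 0.51 and ICS1, the isochorismate synthase of salicylate formation, at 0.42.

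After 0.5 h of light, 155 genes were at least 2-fold higher and 79 at least 2-fold lower in RNAi-21 than in WT. The B-box genes BBX30 (20.09 in WT, 77.3 in RNAi-21) and BBX32 (4.51 and 19.4), both higher in light than in the dark in WT, differed by 1.89. HEI10 differed by 3.24, the P450 of indole defence metabolism CYP71A12 by 2.29 and the galactinol synthase GolS2 by 1.89. Seed storage genes stood at the other end: CRU3 was at 84.7 in WT and 5.51 in RNAi-21, CRA1 at 63.9 and 8.01, and OLEO1, an oil body protein, at 9.34 and 1.1. CRU2 and SESA3 differed by -2.91 and -1.96. The listed seed storage and reserve genes had a median difference of -1.47 over 15 members, with 11 at least 2-fold lower, and this follows their level in the WT library at 0.5 h. The 1 member at least 2-fold higher was EM6, at 1.23, which is named outside the rule. With a pseudocount of 0.1 there were 379 genes higher and 210 lower, and with a filter of 5 there were 48 lower.

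Light signalling and heat shock transcripts were higher in RNAi-21 at 0.5 h, and photosynthesis transcripts were lower. The light signalling list had a median difference of 0.41 (percentile 100, 23 members), with 17 members above and 6 below 0 and 2 at least 2-fold higher. It was led by BBX31 at 1.2, the plastid sigma factor SIG5 at 1.01 and the clock genes PRR9 at 0.95 and CCA1 at 0.81. The heat shock list had a median of 0.71 (percentile 100, 16 members), with the heat shock factor HSFA2 at 1.44, ROF2 at 1.22, MBF1C at 1.2 and HSP101 at 1.06. Light-harvesting genes had a median of -0.54 with 19 of 20 members below 0, among them LHCB1.4 at -1.50, LHCA2 at -1.07 and LHCB1.5 at -1.04. Photosystem genes had a median of -0.58 with 23 of 26 below 0 but none at least 2-fold lower, and PSBO1 differed by -0.93. Carbon fixation genes had a median of -0.53 with 12 of 13 below 0, and GAPA, a glyceraldehyde-3-phosphate dehydrogenase subunit, differed by -0.91. All 3 photosynthesis medians lay at percentile 0.0. The tetrapyrrole median was -0.11 (percentile 5.64), with the chlorophyll pathway regulator FLU at -0.45 and the Mg-chelatase subunit CHLD at -0.42. In the same pair of libraries the root list had a median of -0.17 (percentile 4.12) and the xylem list one of -0.15 (percentile 9.11). Jasmonate genes had a median of 0.28 (percentile 100, 19 members), with VSP2 at 1.19 and JAZ7 at 0.94.

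After 2 h of light, 106 genes were at least 2-fold higher and 41 at least 2-fold lower in RNAi-21. HEI10 was higher by 3.49 and CYP71A12 by 1.83. The seed storage genes CRU3 and CRA1 were higher by 3.33 and 3.27, at FPKM of 12.0 and 17.2 in RNAi-21 against 0.29 and 0.89 in WT, and SESA5 by 2.71. Among the lower genes were U4.2 at -1.44, the tracheary element gene TED7 at -1.27 and SVP at -0.98. The dark-induced asparagine synthetase ASN1 (75.3 in WT, 35.6 in RNAi-21) and the branched-chain aminotransferase BCAT-2 differed by -1.06 and -0.99. With a pseudocount of 0.1 the counts were 326 and 171, and with a filter of 5 they were 70 and 21.

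The photosystem list was higher in RNAi-21 at 2 h, with a median of 0.26 (percentile 99.9) and 24 of 26 members above 0, including ATPD at 0.53 and FD1 at 0.52. Light-harvesting and carbon fixation medians were 0.18 (percentile 92.87) and 0.13 (percentile 76.12). The tetrapyrrole median was 0.10 and turned to -0.01 with totals equalised. The light signalling median was 0.00 and turned to -0.11 with totals equalised. Heat shock genes had a median of -0.24 (percentile 0.36), with the cochaperone BAG6 at -0.89 and HSP101 at -0.74. Auxin response and cell expansion genes had a median of 0.35 (percentile 100, 22 members), and 5 were at least 2-fold higher, among them the growth-promoting SAUR20 at 1.15, SAUR19 at 1.12, SAUR16 at 1.11 and SAUR14 at 1.04. SAUR19 to SAUR24 are near-identical copies, so their separate values are uncertain, as are those of the LHCB1, RBCS and SESA families. Flavonoid genes had a median of 0.32 (percentile 99.99, 14 members), with chalcone synthase CHS at 0.82 and the flavonol regulator MYB111 at 0.65. Jasmonate genes had a median of 0.17 (percentile 99.62), with VSP2 at 1.4 and VSP1 at 0.81. The xylem and root lists were lower, with medians of -0.33 (percentile 0.18) and -0.19 (percentile 0.90).

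**Figure D2:**
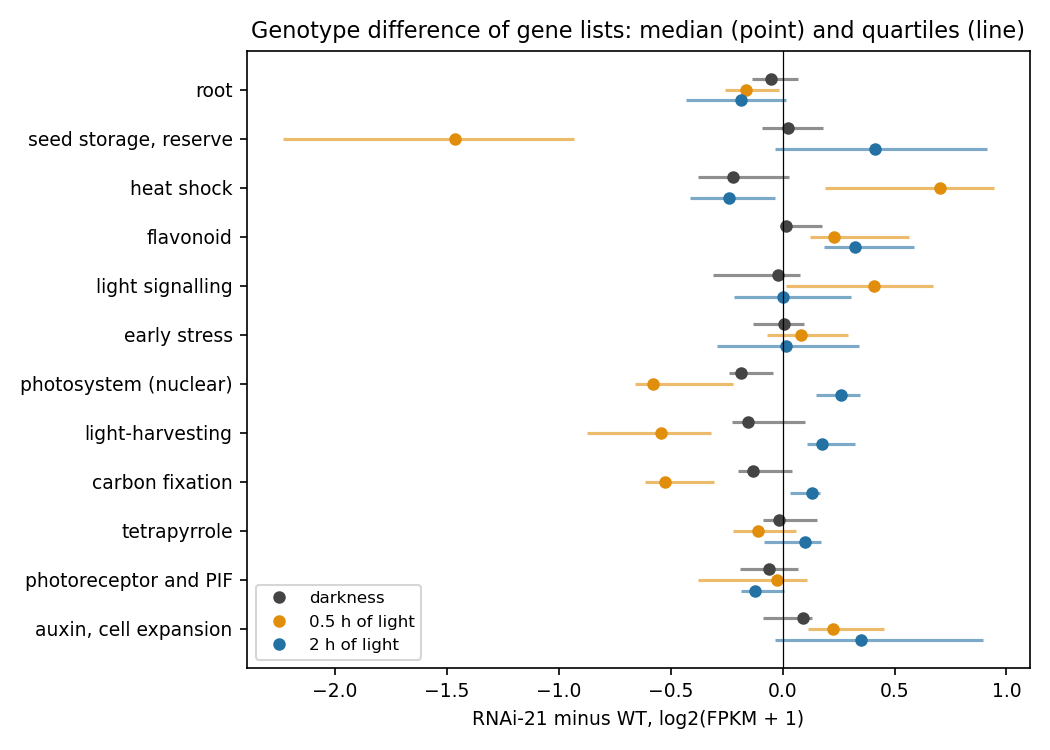
RNAi-21 minus WT on the log2(FPKM + 1) scale for 12 gene lists in the dark, after 0.5 h and after 2 h of light, with points at the median over members and lines from the lower to the upper quartile. At 0.5 h the photosystem median is -0.58 and the heat shock median 0.71, and at 2 h they are 0.26 and -0.24.

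The light comparisons asked how each genotype responded to illumination. No library was kept in the dark for the added time, so light and elapsed time are not separated. In WT after 0.5 h, 151 genes were at least 2-fold higher and 202 at least 2-fold lower than in the dark. BBX30 went from 0.55 to 20.09, and the heat shock factor HSFA6B from 1.24 to 24.2. CRU3, CRA1 and SESA5 had the highest differences, 6.20, 5.65 and 4.42, with FPKM of 0.17, 0.29 and 0.17 in the dark. The growth genes SAUR19 (72.7 to 4.07), SAUR22 (39.7 to 2.90) and SAUR23 (34.7 to 3.97) and the peptide gene RTFL21 (65.5 to 5.53) were lower, and RKD1 went from 17.41 to a listed 0. After 2 h in WT, 1438 genes were at least 2-fold higher and 840 at least 2-fold lower. Flavonoid genes led: flavanone hydroxylase F3H went from 1.33 to 262, CHS from 1.61 to 165, FLS1, a flavonol synthase, from 0.26 to 72.0 and their regulator MYB12 from 0.09 to 71.8. The transporter gene ABCI21 went from 9.22 to 870. RTFL21, SAUR19, RKD1, SAUR22 and RGF6, a root growth factor peptide, were lowest, with RGF6 at 191 in the dark and 10.4 after 2 h.

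In RNAi-21, 329 genes were at least 2-fold higher and 167 lower after 0.5 h, and 1632 higher and 805 lower after 2 h. The genotypes shared 110 genes among the 151 and 329 that were higher at 0.5 h, where independent lists would share 2.69. At 2 h they shared 1209 higher genes (127.26 by chance) and 561 lower genes (36.67 by chance), and no library is common to both sides. Across genes, the responses of the genotypes correlated with Pearson's r of 0.57 and Spearman's rho of 0.33 at 0.5 h, and 0.87 and 0.71 at 2 h, where genes are not independent replicates. With a pseudocount of 0.1, 552 genes were higher and 300 lower in RNAi-21 at 0.5 h, and 337 higher and 389 lower in WT. With organelle-encoded genes left out and totals equalised, 1365 genes were higher and 1092 lower in RNAi-21 at 2 h, a share of 55.6% higher in place of 67.0%.

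Over both genotypes, the additive limma fit gave 228 genes that rose and 271 that fell after 0.5 h, and 3156 that rose and 2914 that fell after 2 h. With totals equalised, 2681 rose and 3291 fell after 2 h, so which direction holds more genes depends on scaling. In the light signalling list 12 of 23 members rose and none fell at 0.5 h, and 21 rose and 2 fell at 2 h. Adjusted over the list alone, 18 rose and 1 fell at 0.5 h. PRR9 rose by 2.88 ± 0.26 (adjusted p = 0.0047, limma) at 0.5 h. HY5, the main regulator of seedling greening, rose by 2.46 ± 0.19 at 0.5 h and by 3.59 ± 0.19 at 2 h. SIG5 and the photoprotective ELIP1 rose by 5.83 and 5.81 at 2 h. In the heat shock list, 5 of 16 members rose at 0.5 h (8 adjusted over the list alone) and 15 at 2 h, with HSP70 (AT3G12580) rising by 4.18 ± 0.31 and the mitochondrial HSP23.6-MITO by 4.12 ± 0.14. Early stress genes rose in 7 of 21 at 0.5 h (13 adjusted over the list alone) and in 12 at 2 h, when 1 fell. DREB2A rose by 3.22 at 0.5 h, and ZAT12 by 3.0 at 2 h.

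Auxin response and cell expansion genes fell at both times, 15 of 22 at 0.5 h (18 adjusted over the list alone) and 19 at 2 h (20 adjusted over the list alone), when 1 rose. SAUR19 had effects of -3.36 ± 0.28 at 0.5 h and -3.70 ± 0.28 at 2 h. Of the 12 dark-expressed photoreceptor and PIF pathway genes, 2 fell at 0.5 h, ATHB2 at -2.03 and PIL1 at -2.51, and at 2 h 6 fell and 3 rose. Adjusted over the list alone, 4 fell and 1 rose at 0.5 h, and 6 fell and 4 rose at 2 h. Flavonoid genes rose in 2 of 14 at 0.5 h, F3H and the flavonoid glucosyltransferase UGT78D2, and in 12 at 2 h (13 adjusted over the list alone). CHS rose by 6.31 ± 0.18 and MYB12 by 6.18 ± 0.17 at 2 h.

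At 0.5 h the light-harvesting median against the dark was 0.07 in WT (percentile 99.53), with 11 members above and 9 below 0. In RNAi-21 it was -0.36 (percentile 0.0), with 17 of 20 below 0 and 3 at least 2-fold lower, and the difference between the genotypes was not tested. The photosystem median was 0.20 in WT (percentile 100) and -0.20 in RNAi-21 (percentile 0.0), and the carbon fixation median 0.24 (percentile 100) and -0.15 (percentile 1.79). The additive fit averages the genotypes: none of the 20 light-harvesting genes passed at 0.5 h, and 12 rose and 1 fell at 2 h, with LHCB2.2 rising by 3.36 ± 0.14 and LHCA1 by 2.51 ± 0.15. In the photosystem list, 1 of 26 rose at 0.5 h, the ferredoxin gene FD1 by 1.09, and 20 rose at 2 h, with PSBS, the photoprotective subunit of photosystem II, up by 2.95 ± 0.13. In the carbon fixation list, 8 of 13 rose at 2 h, with RBCS1B up by 4.2 ± 0.13 and Rubisco activase RCA by 2.32 ± 0.17. In the tetrapyrrole list, 2 of 29 rose at 0.5 h, the Mg-chelatase subunit CHLH by 0.73 and chlorophyllide a oxygenase CH1 by 0.99 (3 adjusted over the list alone). At 2 h 14 rose and 3 fell (15 and 4 adjusted over the list alone), with GUN4, the chelatase activator, up by 2.61, PORA at -2.96 ± 0.18 and PORB at -2.06 ± 0.18. Antioxidant and detoxification genes rose in 13 of 16 at 2 h and in none at 0.5 h, with the alternative oxidase AOX1A up by 2.22 ± 0.13. Carotenoid genes rose in 1 of 15 at 0.5 h, phytoene synthase PSY, and in 11 at 2 h (12 adjusted over the list alone). Of 14 root genes, 1 fell at 0.5 h and 9 at 2 h (10 adjusted over the list alone), with the root hair gene LRX2 at -2.35 and the iron transporter IRT1 at -2.45.

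**Figure D3:**
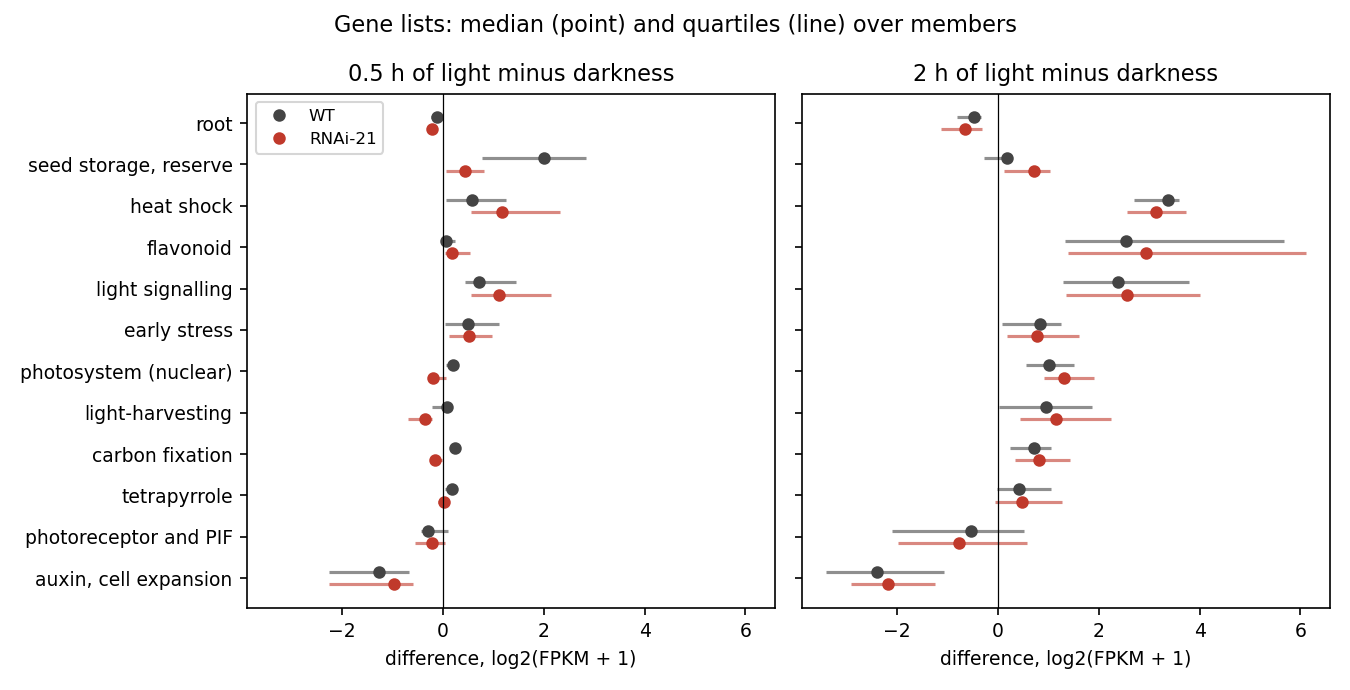
Light minus dark on the log2(FPKM + 1) scale for 12 gene lists after 0.5 h (left) and 2 h (right), WT in grey and RNAi-21 in red, with points at the median over members and lines from the lower to the upper quartile. At 2 h the heat shock medians are 3.37 in WT and 3.14 in RNAi-21, and the auxin medians -2.40 and -2.19.

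The difference of the light response between the genotypes was not tested, since it rests on 1 library per corner. At 0.5 h the response of 171 genes was higher by at least 1 in RNAi-21 and that of 77 was lower. At 2 h it was higher for 180 genes and lower for 124. At 0.5 h the heat shock response differed by a median of 0.90 (percentile 100), with medians of 0.57 in WT and 1.16 in RNAi-21, and 5 members differed by at least 1. The light signalling response differed by 0.61 (percentile 100), and the light-harvesting and photosystem responses by -0.45 and -0.33 (percentile 0.0 for both). The seed list differed more, by -1.35 (percentile 0.0), with 9 of 15 members lower and 1 higher by at least 1, and this rests on its level in the WT library at 0.5 h. At 2 h the photosystem response differed by 0.41 (percentile 99.98), with medians of 1.00 in WT and 1.31 in RNAi-21. With organelle-encoded genes left out and totals equalised, 120 genes were higher and 269 lower at 2 h, which moves the share of higher calls from 59.2% to 30.8%. That setting shifts the median of all genes to -0.14, against 0.01 for the values as deposited.

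The genotype differences at the 3 times were compared with each other across genes. Across genes, the difference in the dark and that at 0.5 h correlated with Pearson's r of 0.35 and Spearman's rho of 0.36. For 0 h and 2 h the values were 0.07 and -0.06, and for 0.5 h and 2 h both were 0.27. These are descriptions across genes, and the 3 comparisons share no library. Each difference rests on 1 library per side, and noise lowers such correlations. They therefore do not show how far the genotype effect changed with light. Of the 31 genes at least 2-fold higher in the dark, 14 were also higher at 0.5 h (0.26 by chance) and 14 at 2 h (0.18 by chance). Of the 73 lower genes, 19 and 12 were lower at those times (0.31 and 0.16 by chance). At all 3 times, 9 genes were at least 2-fold higher, among them HEI10 and XTH7, and 5 were at least 2-fold lower. None of the 5 was given a symbol. Named outside the rule, they include ATCG00720 and ATCG00730 of the plastid and ATMG00090 of the mitochondrion, which matched no entry of the name table.

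The listed organelle-encoded genes held a smaller share of the summed FPKM in the RNAi-21 libraries. Only 15 plastid-encoded and 40 mitochondrion-encoded identifiers were listed, so the shares cover these and not all organelle transcripts. Plastid-encoded genes held 0.0279%, 0.0221% and 0.0270% of the summed FPKM in WT at 0, 0.5 and 2 h, and 0.00871%, 0.0115% and 0.0187% in RNAi-21. Mitochondrion-encoded genes held 0.227%, 0.197% and 0.211% in WT and 0.119%, 0.138% and 0.179% in RNAi-21. The median difference over 14 plastid-encoded genes was -1.41 in the dark, -1.09 at 0.5 h and -0.39 at 2 h, and over 22 mitochondrion-encoded genes -0.92, -0.47 and -0.19. In the limma fit over the 3 times, 1 plastid-encoded and 3 mitochondrion-encoded genes fell over all genes tested. Adjusted over the list alone, 10 and 14 fell and 1 gene in each group rose. Both groups were formed after the data were seen, so the counts over the list alone are a description and no added support. Small nuclear and nucleolar RNA genes had medians of -0.19, -0.44 and 0.12 at the same times, the last turning to -0.05 with totals equalised.

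**Figure D4:**
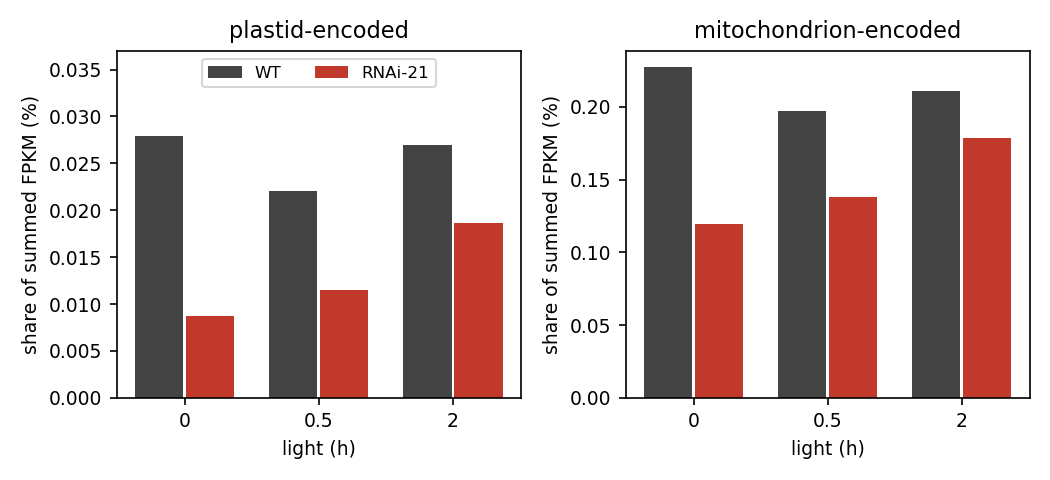
Share of the summed FPKM, in percent, held by the listed plastid-encoded (left) and mitochondrion-encoded (right) genes. Bars are the 6 libraries, WT in grey and RNAi-21 in red, against hours of light. The plastid share in the dark is 0.0279% in WT and 0.00871% in RNAi-21.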

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

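All tests in this part were chosen after the values were seen. Results stand here because the median of a gene list lay beyond the random lists in opposite directions at different light times, and with 1 library per group the difference between times was not tested. Photosystem genes had medians of -0.186 in the dark, -0.58 at 0.5 h and 0.26 at 2 h (RNAi-21 minus WT). Heat shock genes had medians of -0.22, 0.705 and -0.238 at these times. Seed storage and reserve genes had medians of -1.465 at 0.5 h and 0.411 at 2 h.

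The first pattern is the genotype difference at 0.5 h, where light-induced and heat shock transcripts were higher in RNAi-21 and photosynthesis transcripts lower. A light response further along in the RNAi-21 sample could account for the induced part. Outside the lists, 1327 genes at least 2-fold higher in WT after 2 h had a median genotype difference of 0.233 at 0.5 h. It was -0.041 for unresponsive genes and -0.088 for 810 genes lower after 2 h. In the dark the 810 genes were at -0.094, but they were picked with the same WT dark library, which by itself lowers that value. The 46 light-harvesting and photosystem genes had a median of -0.562 (upper quartile -0.26), although they were higher after 2 h. These values argue against a response further along for the photosystem genes, whose WT median was already 0.20 above the dark at 0.5 h. They cannot decide for the light-harvesting genes, of which 9 of 20 lay below 0 in WT at 0.5 h, before the rise. A response further along is also argued against for the light-repressed auxin genes, with a median of 0.226 (lower quartile 0.11). Library scaling is argued against by the median of all genes, -0.027. A larger share of root or xylem in the RNAi-21 sample is argued against by the root and xylem genes, of which 18 of 23 were lower (median -0.152, upper quartile -0.07). Among them PYK10 was higher by 0.71, and by 0.60 in the dark. A lower share of green tissue is not settled by these genes, since no list was fixed for the hypocotyl, the seedling stem, and the auxin and cell expansion genes were higher. A genotype-dependent light response and a difference of 1 sample, such as the WT sample at 0.5 h with its seed signal, stay open, untested.

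The second pattern is the seed storage signal in the WT library at 0.5 h, where the listed seed genes had a median of 2.00 above 0 h. Of 15 members 14 lay above 0, and EM6 went the other way, from 7.92 to 5.11. A light response of similar size in both genotypes is argued against by RNAi-21, where the median was 0.437 and the upper quartile 0.81. Seed material or late-germinating seeds in that sample may account for it, as the WT median was 0.17 at 2 h, but 12 seed-type genes outside the list had a median of 0.033 with 7 above and 5 below 0. Among these, SESA5 and AT4G26740, near 0 in the dark, were higher, from 0.17 to 24.0 and from 0.03 to 1.70, and most others were already expressed in seedlings and could hide a small share. This explanation therefore cannot be told apart from a light response stronger in WT at 0.5 h, since the smaller RNAi-21 median also lay at percentile 100, but at 2 h the RNAi-21 median was the higher, 0.71.

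The third pattern is the lower level of the listed organelle-encoded transcripts in RNAi-21. An effect on plastid transcripts alone is argued against by the mitochondrion-encoded genes, whose median in the dark was -0.923 (upper quartile -0.32). Less RNA without a poly(A) tail in the RNAi-21 libraries could lower both, and small nuclear and nucleolar RNA genes had a median of -0.185 in the dark. Their quartiles in the dark, -0.41 and 0.10, span 0. At 0.5 h their median was -0.438 with both quartiles below 0 (-0.811 and -0.075), and at 2 h it was 0.117 with quartiles of -0.084 and 0.467. Less RNA without a poly(A) tail therefore cannot be told apart from an effect of the genotype on both organelles, which was not tested.

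For the genotype effect, 1 of the 10 splits of the 6 libraries, the real one, gave as many as 31 genes. The highest count among the others was 17, given by both splits with the 0 h libraries on 1 side and the 2 h libraries on the other. With light time in the fit they are the same comparison, RNAi-21 with WT at 0.5 h alone, and are not free of the genotype difference. All splits that do not part every light time repeat in pairs in this way, so the 10 splits are not 10 separate comparisons. The other splits that part every light time gave 0, 1 and 0 genes. With 10 splits, a share under 0.05 cannot be reached.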

How the results depend on the processing

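A pseudocount of 0.1 counts weak genes more. RNAi-21 against WT it gave 131 higher and 231 lower in the dark, 379 and 210 at 0.5 h, and 326 and 171 at 2 h. For light it gave 337 higher and 389 lower (WT, 0.5 h), 1316 lower (WT, 2 h), 552 and 300 (RNAi-21, 0.5 h) and 1320 lower (RNAi-21, 2 h), and for the response difference 474 higher and 269 lower at 0.5 h and 510 and 417 at 2 h. A filter of 5 gave 20 and 42 in the dark, 48 lower at 0.5 h, 70 and 21 at 2 h, and for the response difference 112 and 41 at 0.5 h and 86 higher at 2 h. At 4-fold, RNAi-21 against WT had 5 higher and 9 lower in the dark, 10 and 12 at 0.5 h, and 11 and 6 at 2 h. Light had 33 and 32 (WT, 0.5 h), 450 and 157 (WT, 2 h), 76 and 20 (RNAi-21, 0.5 h) and 511 and 132 (RNAi-21, 2 h), and the response difference 9 and 13 at 0.5 h and 11 and 9 at 2 h. Fewer genes pass a stricter filter or threshold by construction. With organelle genes left out and totals equalised, the response difference at 2 h had 269 lower genes. This follows from equalising the totals, since the listed organelle genes hold at most 0.227% (mitochondrial) and 0.0279% (plastid) of a library's summed FPKM.

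The genotype effect had 10 genes higher and 5 lower without a variance trend, 5 and 2 without a light time term, 136 and 40 without the 0 h libraries, 88 and 67 without the 0.5 h libraries, and 3 and 3 without the 2 h libraries. The cause was not tested, and a fit without 1 of the times has only 1 residual degree of freedom. Of the 31 genes, 31 passed without the 0 h or 0.5 h libraries and 5 without the 2 h libraries, and these fits are no independent check. Median-ratio scaling, no filter and leaving out the seed list (chosen after seeing the data) kept all 24 counts within 1.5 times. The added fits of the light effects without a variance trend or without the other light time did so too. Under alternatives 775 list medians stayed within 1.5 times or 0.1 and 42 moved further. Several medians near 0 changed sign, and so did 2 that lay beyond the random lists: the salicylate list in RNAi-21 at 2 h of light, -0.476, was 0.046 with a filter of 5, and small nuclear and nucleolar RNA genes at 2 h, 0.117, were -0.048 with totals equalised, and the cause was not tested. No gene named as passing the genotype test changed sign, and HEI10 passed under every alternative. U4.2 also lost its call with no filter, a filter of 5 or totals equalised, and VSP2 with a filter of 5. DESeq2 was not run, since the values are not counts. Pairing by replicate was not possible because each group has 1 library without a replicate number, but the additive fit compares the genotypes within each light time. Depth is unknown, so the limits it sets on weak genes are unknown.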

Other observations

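Differences between the genotypes were small in most of the remaining lists. Ethylene genes had medians between -0.07 and -0.06 at the 3 times over 10 members, with the ethylene feedback gene EBF2 at -0.53, -0.70 and -0.27. Carotenoid genes had medians of -0.08, -0.08 and -0.10 over 15 members, of which 10, 10 and 11 lay below 0, and plastid transcription genes 0.12, -0.04 and -0.10 over 18, where the value at 0.5 h turned to 0.01 with totals equalised. Photoreceptor and PIF pathway genes had a median of -0.06 in the dark, which turned to 0.00 with totals equalised, and -0.12 at 2 h. Salicylate genes had medians of 0.12 at 0.5 h and -0.02 at 2 h, the latter turning to 0.01 under median-ratio scaling, and NIMIN1 differed by -1.61 at 2 h. Antioxidant genes had a median of -0.15 in the dark, with 14 of 16 below 0, and -0.09 at 2 h (percentile 0.74), and the iron store gene FER1 differed by -0.63 in the dark and -0.60 at 0.5 h. Early stress genes, which include singlet oxygen responses, had medians of 0.01, 0.08 and 0.01, with RRTF1 at 0.91 at 0.5 h and BAP1 at 0.79 at 2 h, and the 2 h median turned to -0.06 with totals equalised. Cell cycle genes had medians of -0.13, 0.00 and -0.09 over 11 members, the middle value turning to 0.05 with totals equalised, and stomatal lineage genes -0.27, -0.19 and 0.12 over 4.

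In light, over both genotypes, jasmonate genes rose in 7 of 19 at 2 h in the limma fit (7 rose and 2 fell adjusted over the list alone), with JAZ1 up by 2.00 ± 0.14 and CYP94B3 by 2.07 ± 0.22. The hook regulator HLS1 fell at both times, by 0.96 and 1.38 on the log2 scale, in an ethylene list where 2 of 10 genes fell at each time (and 1 rose at 0.5 h adjusted over the list alone). Plastid transcription genes rose in 9 of 18 at 2 h (10 rose and 1 fell adjusted over the list alone), led by SIG1 at 1.65 ± 0.12. In the salicylate list 4 of 13 rose and 3 fell at 2 h, 3 of 11 cell cycle genes fell (1 adjusted over the list alone), and 2 of 9 xylem genes fell, among them the cellulose synthase IRX5 at -1.73.

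Some genes without a symbol are named here after their values were seen. AT2G05660, annotated as a pseudogene, had 81.7, 68.6 and 70.5 FPKM in WT at 0, 0.5 and 2 h. In RNAi-21 it had 0.17, 0.25 and 0.37 (effect -5.89, adjusted p = 7.9e-06, limma). The non-coding RNA gene AT4G04223 was at 29.2 in WT and 104 in RNAi-21 in the dark (effect 2.00, adjusted p = 0.0014, limma). The pseudogene AT1G43590 was at 8.42 and 31.9 (effect 1.95), and the transcribed pseudogene AT3G06433 at 9.39 and 1.4 (effect -2.27). A sequence or background difference between the lines at these loci was not examined, and no other RNAi line was measured. AT4G14280 was listed at 41.0 in WT at 2 h, at 6.0 in RNAi-21 at 0.5 h and at 0 in the other 4 libraries. PYK10, a beta-glucosidase of the root list, was among the abundant transcripts, from 3478 to 4936 FPKM in WT and 5703 to 6889 in RNAi-21, in samples whose tissue label is leaf.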
